A study of Mus musculus with 21 samples.

How the data were processed

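RNA of 21 libraries of mouse splenic CD19+ cells was measured by sequencing of stranded mRNA libraries read as single ends, in 7 groups of 3. Per the labels the cells were harvested at time zero or kept for 3 h in medium with 20 mM HEPES, with no addition, with 5 mM HOAc, or with HOAc and either collagen type I at 200 µg/ml, collagen type V at 200 µg/ml, LPS at 10 µg/ml or anti-IgM F(ab')2 at 10 µg/ml. The replicates carried the numbers 3, 4 and 5, and each number stood for 1 spleen harvest that was used in all 7 conditions. Libraries were sequenced mixed over lanes per the labels, and no batch other than the harvest was given.

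The deposited file was a workbook with 1 table of 3676 genes and a legend. Per the file headers and legend, the authors gave read counts per gene and library without normalization. The authors also gave CPM (counts scaled by library size), whose divisor was the same for all genes of a library and larger than the sum of the deposited counts. The authors gave log2 fold changes of col(I), col(V), anti-IgM and LPS against HOAc, and deposited a p-value and a false discovery rate for each. The submitters' processing notes named Trim Galore, STAR, featureCounts and edgeR with genome build mm10, and the versions of these tools are not given in the sources used here. From the ratio of the deposited FDR to the p-value the authors had tested 12169 genes, of which the table held 30.2%, and all genes in it had an FDR under 0.001 for both LPS and anti-IgM.

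In the deposited table the block of counts and CPM sat 1 line above the block of gene names and statistics. With the counts moved by 1 line, the log2 ratios of group mean CPM lay within 0.05 of the authors' log2 fold changes for 100.0% of genes for col(I), 99.9% for col(V), 99.9% for anti-IgM and 99.8% for LPS, against 32.5%, 20.5%, 11.5% and 3.14% as deposited. This used genes with a mean of at least 1 CPM in both groups. B cell markers had a median of 548.5 CPM after the move and 51.2 CPM before. All counts were used after the move, which left 3675 genes with counts and 1, Pdcd1lg2, without. Gene symbols were matched to GENCODE M21, where 3536 were found and 140 were not, and coordinates are those of mm10.

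The fit used edgeR 4.0.16 in R 4.3.3, with the counts of all 21 libraries, 1 mean per group, glmQLFit and glmQLFTest with robust estimation, and Benjamini-Hochberg adjustment over the 3675 genes. A gene passed at an adjusted p under 0.05, and filterByExpr kept all 3675. Library sizes were those implied by the authors' count and CPM, 33.68 to 48.14 M, since the deposited genes were a selection that moved with the stimuli. Whether these sizes held normalization factors was not tested. This scaling was chosen after the data were examined. TMM over the deposited genes had been planned before and was run as an alternative. Fold changes are given as log2 with the standard error of the model. The common dispersion was 0.00801 with 14 residual degrees of freedom. The CPM of a group is given as mean with SD over 3 libraries.

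Comparisons were untreated 3 h against time zero, HOAc against untreated 3 h, each of col(V), col(I), LPS and anti-IgM against HOAc, col(V) against each of the other 3, and LPS against anti-IgM. The comparisons, the tests, 32 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the report names, for each comparison, the 8 largest rises and the 8 largest falls (4 of each for HOAc against untreated 3 h, the comparisons between treatments, and all that passed for col(I)) among genes with an adjusted p under 0.05, a mean of at least 5 CPM over the 2 groups, the same sign in all 3 harvests and no predicted or clone symbol. It further names up to 4 members with the smallest p of each list described, and members of the lists on NF-kB, cytokines, Toll-like receptors, activation, collagen receptors and other cell types. Genes outside the rule are said to be chosen after their values were seen.

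The 32 lists held 543 genes, of which 201 were measured. They covered NF-kB, cytokines, Toll-like receptors, immediate early genes, activation, resting B cells, B cell receptor signalling, interferon, ribosome biogenesis, cholesterol, unfolded protein response, heat shock, glycolysis and hypoxia, p53, antioxidants, acetate and fatty acids, collagen receptors, inflammasome, cell cycle, mitochondrially encoded and ribosomal protein genes, and markers of B, marginal zone B, T, NK, dendritic, plasma, erythroid and stromal cells, macrophages, neutrophils and platelets. The 19 lists with at least 5 measured members were tested with camera in limma 3.58.1 at the preset correlation of 0.01, adjusted over 190 tests, and with the correlation estimated for each list beside it. The estimate came from the fit without the harvest. Members were also adjusted over the list alone. After the data were examined 8 further lists were formed from gene symbols, and the closing section gives them.

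Overlaps of responses were counted as genes that passed in the same direction in 2 comparisons with HOAc, beside the count under independence. They were set against 30 simulations of unchanged groups that shared the HOAc libraries, which draw libraries independently. The fit was tested on simulated data with the means and dispersions of these libraries, in which 50 genes each changed 1.2-fold, 1.5-fold, 2-fold and 4-fold. For col(V) against HOAc 10, 44, 48 and 49 of these were found and 6 of 3475 unchanged genes passed, and for col(I) against HOAc 11, 39, 48 and 50 were found and 7 unchanged genes passed. The harvests were checked for pairing by correlating the deviations of libraries from their group means, where the median r was 0.240 between libraries of 1 harvest (46 of 63 pairs above 0.1) and -0.116 between libraries of different harvests.

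Alternatives fixed before the data were examined were DESeq2 size factors, no filter, a mean of at least 5 CPM, the harvest as a block, each library left out in turn, the 6 libraries of the 2 groups alone, the Wald test of DESeq2 1.42.0, an estimated correlation in camera and the untreated cells as control of the overlaps. Fits that left out a library or used 6 libraries had no block for the harvest. Adjustment over the 12169 genes the authors tested and leaving out libraries for gene lists and overlaps were added after seeing the data, and TMM, planned as the scaling, became an alternative then. That adjustment took the p-values of the 3675 genes and counted 12169 tests, as if all other p-values were larger. A pseudocount was not needed, since counts were deposited. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The 14 deposited columns of group means, and raw reads, were not used here, and the deposited fold changes and FDR served only for checks and comparison.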

Results

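Gene expression was measured by RNA sequencing in mouse splenic B cells that were exposed to collagen, bacterial lipopolysaccharide or an antibody against their antigen receptor. CD19+ cells were taken from spleens of male C57BL/10 mice by magnetic sorting, and 21 libraries fell into 7 groups of 3. The groups were cells at time zero, cells kept for 3 h with no addition, and cells kept for 3 h with 5 mM acetic acid (HOAc, the solvent of the collagens), with collagen type I (col(I)) or type V (col(V)) at 200 µg/ml, with lipopolysaccharide (LPS) at 10 µg/ml, or with anti-IgM F(ab')2 at 10 µg/ml. Per the labels, each replicate number stood for a separate spleen harvest that was used in all 7 conditions, so the 3 replicates were separate harvests.

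The library sizes implied by the deposited counts and the CPM values (counts scaled to a common library size) were between 33.68 and 48.14 M. They reached from 40.63 to 47.53 M at time zero, 39.77 to 47.05 M in untreated cells, 41.92 to 48.14 M with HOAc, 42.39 to 45.36 M with col(I), 40.36 to 46.99 M with col(V), 33.68 to 43.29 M with LPS and 38.91 to 43.56 M with anti-IgM. The deposited table held 14.15 to 23.1 M counts per library on 3675 genes. These genes were 30.2% of the 12169 genes that the authors tested, and all of them had an authors' FDR under 0.001 for both LPS and anti-IgM. The table was therefore a selection of genes that answered both stimuli, and genes outside it were not analysed here. Whether the divisor of the CPM held normalization factors besides the number of reads was not tested. If it held none, the genes of the table took 52.2 ± 1.06% (SD, n = 3) of all CPM with LPS and 36.2 ± 0.0929% with HOAc.

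Across the 3675 genes the first principal component carried 78.0% of the variance and the second 13.8%. LPS libraries lay at 67.3 to 70.1 on the first component, anti-IgM libraries at 13.97 to 18.75, and time zero libraries at -44.8 to -43.3. Col(V) libraries lay at -11.9 to -3.82 and HOAc libraries at -17.2 to -8.47, and in each harvest the col(V) library lay above its HOAc library. The biological coefficient of variation was 0.0895. TMM and DESeq2 scaling over the deposited genes moved the median change of culture by -0.12 and -0.14 on the log2 scale, that of LPS by -0.14 and -0.031 and that of anti-IgM by -0.10 and -0.090.

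The first comparison asked what 3 h of culture did to freshly sorted cells (n = 3 libraries per group, log2 fold change ± SE throughout). Among the genes that rose, Trib3, a pseudokinase under the transcription factor ATF4, rose by 5.93 ± 0.29 on the log2 scale, from 1.05 ± 0.202 to 64.0 ± 18.7 CPM (SD). Chac1, which breaks down glutathione, rose by 6.02 ± 0.34, the glycine carrier Slc6a9 by 6.19 ± 0.25, and Asns, which makes asparagine, by 4.90 ± 0.16. The growth factor Vegfa rose by 5.61 ± 0.17 and the nuclear receptor Nr4a2, an early response gene, by 6.06 ± 0.57. The amino acid carrier Slc1a4 rose by 5.76 ± 0.17, the interleukin 1 decoy receptor Il1r2 by 5.22 ± 0.25 and Cables1, which binds cyclin-dependent kinases, by 5.04 ± 0.21. Among the genes that fell, Tlr3, a receptor of double-stranded RNA, had a log2 change of -4.52 ± 0.16, the antiviral gene Mx1 -3.60 ± 0.14, the adhesion molecule Vcam1 -3.77 ± 0.19 and the inhibitory receptor Cd22 -2.26 ± 0.10. The transporter Abcg3 had -4.41 ± 0.16, the chaperone Hspa12a -4.13 ± 0.20, the membrane protein Lrrc25 -3.73 ± 0.16, Asb2, of a ubiquitin ligase, -3.68 ± 0.20 and Slfn5, an interferon-induced gene, -3.59 ± 0.26.

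Under the fixed gene lists, stress and growth genes rose in culture and interferon and B cell receptor signalling genes fell. Of 10 measured unfolded protein and integrated stress response genes 8 rose and 0 fell (camera adjusted p = 2.8e-04, adjusted p = 0.63 with an estimated correlation). All 26 ribosome biogenesis genes rose, with a median of 0.87 (camera adjusted p = 6.8e-05, adjusted p = 0.728 with an estimated correlation). Immediate early genes, the first transcribed after a stimulus, rose in 9 of 10 cases (camera adjusted p = 0.0046, adjusted p = 0.63 with an estimated correlation). Interferon-stimulated genes fell in 9 of 9 (camera adjusted p = 2.0e-05, adjusted p = 0.214 with an estimated correlation), B cell receptor signalling genes in 10 of 13 (camera adjusted p = 9.1e-04, adjusted p = 0.214 with an estimated correlation). Toll-like receptor components fell in 4 of 6 (camera adjusted p = 7.8e-04, adjusted p = 0.214 with an estimated correlation) and marginal zone B cell markers in 5 of 5 (camera adjusted p = 0.0115, adjusted p = 0.201 with an estimated correlation). NF-kB pathway and feedback genes rose in 7 of 9, without a call for the list (camera adjusted p = 0.0797, adjusted p = 0.63 with an estimated correlation). Counts adjusted over the list alone were equal to these for each of the 8 lists, and with an estimated correlation 0 lists were called. Markers of other cells, too few for a list test, moved as well, as 3 of 3 macrophage markers fell (median -1.50), the stromal marker Pecam1 had a log2 change of -1.52 ± 0.12 and 2 of 3 plasma cell markers rose (median 1.92).

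By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2994 of 3675 genes passed after 3 h of culture, 1788 higher and 1206 lower, and 827 of them moved at least 2-fold. The balance of rises and falls hung on the scaling, with 1490 higher and 1414 lower under DESeq2 size factors and 1551 and 1366 under TMM. The design does not separate time in culture from the handling of the cells.

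The second comparison asked what the solvent did, since the collagens were given in HOAc (n = 3 per group). HOAc lowered cholesterol synthesis genes at the preset correlation, while the list was not called with an estimated one (adjusted p = 0.63). Among the genes that rose, the linker histone gene Hist1h1c had a log2 change of 2.00 ± 0.21, the antigen-presenting Mr1 1.86 ± 0.15, the phospholipase-like Plcxd1 1.65 ± 0.15 and Myadm, a membrane protein, 1.61 ± 0.10. Tnf rose by 1.43 ± 0.15 and Lta by 1.16 ± 0.13, both cytokines, though 2 of 7 cytokine and chemokine genes rose and the list was not called (camera adjusted p = 0.205, adjusted p = 0.63 with an estimated correlation). Ffar3, a receptor of short fatty acids such as acetate, rose by 1.93 ± 0.23, and Elovl6, which lengthens fatty acids, by 1.61 ± 0.16. Txnip, which restrains glucose uptake and binds thioredoxin, rose by 0.98 ± 0.078, from 306 ± 5.26 to 604 ± 33.2 CPM (SD). It belongs to the resting B cell genes, of which 3 of 11 rose and 1 fell, without a call (camera adjusted p = 0.238, adjusted p = 0.707 with an estimated correlation). Aven, an inhibitor of apoptosis, fell with a log2 change of -1.53 ± 0.14, Tbc1d30 with -1.45 ± 0.19, Ank, a pyrophosphate carrier, with -1.38 ± 0.10 and Slc25a26, a mitochondrial carrier, with -1.36 ± 0.13.

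All 10 measured cholesterol synthesis genes fell with HOAc, with a median of -0.62 (camera adjusted p = 2.8e-04, adjusted p = 0.63 with an estimated correlation). Among ribosome biogenesis genes 6 of 26 fell (camera adjusted p = 0.0035, adjusted p = 0.781 with an estimated correlation), and 15 fell with the harvest as a block. Toll-like receptor components rose in 5 of 6 (camera adjusted p = 0.0435, adjusted p = 0.618 with an estimated correlation), a call that ended without untreated replicate 3 (adjusted p = 0.0589), untreated replicate 4 (0.0627) or HOAc replicate 5 (0.0613). Of the 11 acetate, fatty acid synthesis and pH genes 4 rose and 2 fell (camera adjusted p = 0.347, adjusted p = 0.63 with an estimated correlation). Counts adjusted over the list alone were equal for these 4 lists. Of the markers of other cells, 2 of 3 macrophage markers rose with HOAc (median 0.30), Pecam1 had a log2 change of 0.49 ± 0.12 and 2 of 3 plasma cell markers fell (median -0.80). In all, 1587 genes passed, 868 higher and 719 lower, and 96 of them moved at least 2-fold. The larger share turned with the scaling, as 764 were higher and 850 lower under DESeq2 size factors and 802 and 804 under TMM.

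The third comparison asked what col(V) did beyond its solvent (n = 3 per group). In the fit without the harvest 36 genes passed, and with the harvest as a block 205 did. Nfkbid, a nuclear IkB protein that steers NF-kB, rose by 0.77 ± 0.12 on the log2 scale, from 213 ± 14.1 to 364 ± 53.9 CPM (SD), and the growth regulator Myc rose by 0.67 ± 0.11, from 193 ± 22.8 to 308 ± 23.1 CPM. Txnip fell with a log2 change of -1.19 ± 0.078, from 604 ± 33.2 to 265 ± 19.3 CPM. Tgm2, an enzyme that cross-links proteins, rose by 1.56 ± 0.20, Vcam1 by 1.49 ± 0.18 and Axl, a receptor kinase for Gas6, by 1.08 ± 0.14. These 3 genes reached 21.5 ± 7.73, 13.6 ± 2.85 and 10.7 ± 2.34 CPM with col(V), against 7.27 ± 1.19, 4.82 ± 0.926 and 5.04 ± 0.879 CPM with HOAc. The cytokine gene Il1b rose by 0.96 ± 0.21, Cdk5r1, an activator of Cdk5, by 0.65 ± 0.13, and Mir155hg, the host gene of microRNA 155, by 0.47 ± 0.10.

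Falls with col(V) after Txnip were smaller. Mmp11, a metalloproteinase, had a log2 change of -0.65 ± 0.14, Idh1, the isocitrate dehydrogenase of the cytosol, -0.63 ± 0.11, the Polycomb gene Cbx8 -0.55 ± 0.12, the GTPase gene Gimap7 -0.55 ± 0.10, the acid amidase gene Naaa -0.54 ± 0.081, the interferon-induced GTPase gene Igtp -0.53 ± 0.10 and Ddah2, which degrades methylarginines, -0.53 ± 0.12. In mm10, Nfkbid lies at chromosome 7, 30421732 to 30428746, Myc at chromosome 15, 61985391 to 61990374, Txnip at chromosome 3, 96557957 to 96561883. Tgm2 lies at chromosome 2, 158116402 to 158146436, Vcam1 at chromosome 3, 116109949 to 116129688 and Axl at chromosome 7, 25757273 to 25788705. The adjusted p values in edgeR's quasi-likelihood test were 2.0e-08 for Txnip, 1.6e-04 for Vcam1, 2.7e-04 for Tgm2, 2.7e-04 for Axl, 0.00178 for Nfkbid and 0.00281 for Myc, and each of the 16 genes named moved the same way in all 3 harvests.

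**Figure D1:**
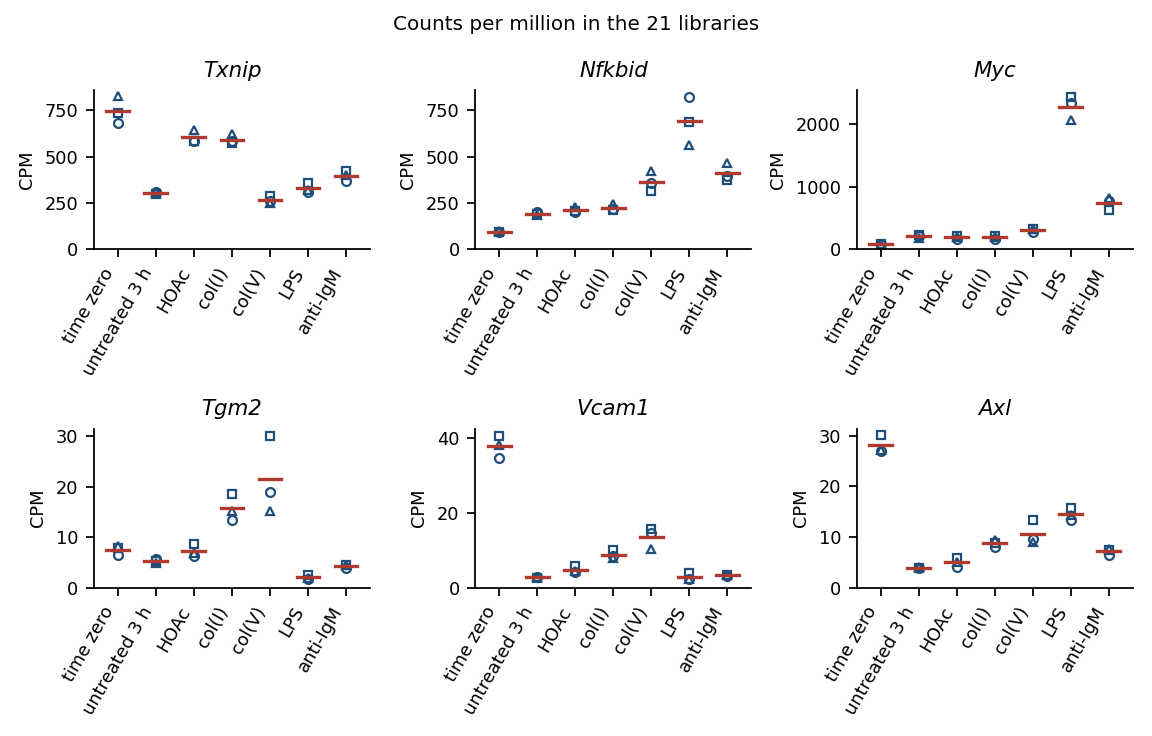
CPM (vertical axis, linear, from 0) of 6 genes in the 21 libraries by group (horizontal axis). Circles, squares and triangles are replicates 3, 4 and 5, and bars are group means. Mean Txnip was 265 CPM with col(V) and 592 CPM with col(I), while Tgm2 was 21.5 and 15.7 CPM with the 2 collagens and 7.27 CPM with HOAc.

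Small shifts of whole gene lists went with these changes. NF-kB pathway and feedback genes moved up by a median of 0.21 (camera adjusted p = 3.6e-07, adjusted p = 0.078 with an estimated correlation). Over all genes 2 of 9 rose, Nfkbid and Nfkbiz (log2 change 0.38 ± 0.082), and adjusted over the list alone 6 did. The list of B cell activation genes moved up by a median of 0.25 (camera adjusted p = 3.2e-05, adjusted p = 0.078 with an estimated correlation). Of its 15 genes 3 rose, which were Myc, the surface protein Cd83 (log2 change 0.38 ± 0.072) and the lymph node homing receptor Ccr7 (0.38 ± 0.080), and adjusted over the list alone 7 rose and 1 fell. Immediate early genes moved up (camera adjusted p = 0.0114, adjusted p = 0.63 with an estimated correlation) with 0 of 10 passing, 1 adjusted over the list alone and 4 with the harvest as a block. The 26 ribosome biogenesis genes moved up by a median of 0.10 (camera adjusted p = 0.00688, adjusted p = 0.781 with an estimated correlation), with 0 genes passing over all genes and 0 adjusted over the list alone.

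Downward shifts with col(V) covered resting B cell genes and interferon-stimulated genes. Resting B cell genes moved by a median of -0.12 (camera adjusted p = 0.00123, adjusted p = 0.214 with an estimated correlation), where Txnip was the 1 gene of 11 to fall, and the 1 to fall adjusted over the list alone. Interferon-stimulated genes moved by -0.25 (camera adjusted p = 2.3e-04, adjusted p = 0.329 with an estimated correlation), with 0 of 9 passing over all genes and 6 falling adjusted over the list alone, and 5 with the harvest as a block. Mx1 had a log2 change of -0.48 ± 0.14 and Stat2, a transducer of interferon signals, -0.25 ± 0.077, and with the harvest as a block their adjusted p values were 0.0492 and 0.0382. The call for immediate early genes ended without HOAc replicate 3 (adjusted p = 0.137) and without col(V) replicate 4 (0.0650) or 5 (0.0746), and that for ribosome biogenesis genes without col(V) replicate 4 (0.529) or HOAc replicate 5 (0.303).

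Integrin and collagen receptor genes did not pass with col(V) (0 of 7 rose and 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.135, adjusted p = 0.48 with an estimated correlation), and the list was called without col(V) replicate 4 (adjusted p = 0.0340). Among the 7 cytokine and chemokine genes Il1b was the 1 to rise, against 2 adjusted over the list alone (camera adjusted p = 0.0764, adjusted p = 0.486 with an estimated correlation). Irak2, a kinase of Toll-like receptor signalling with a log2 change of 0.28 ± 0.058, was the 1 of 6 Toll-like receptor components to rise, over all genes and adjusted over the list alone (camera adjusted p = 0.969, adjusted p = 0.981 with an estimated correlation). Dhcr7, of cholesterol synthesis, fell with a log2 change of -0.46 ± 0.081, the 1 of 10 in its list under either adjustment (camera adjusted p = 0.0797, adjusted p = 0.76 with an estimated correlation), and that list was called lower without col(V) replicate 4 (adjusted p = 0.00118) or HOAc replicate 5 (0.00238).

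Of 3675 genes 36 passed for col(V) against HOAc, 19 higher and 17 lower, and 553 had an unadjusted p under 0.05. With the harvest as a block 205 passed, 83 higher and 122 lower, and these held all 36. The DESeq2 Wald test gave 155, and adjustment over the 12169 genes that the authors tested gave 17. The authors' deposited FDR passed the same threshold for 242 of these genes, which held all 36 and 198 of the 205. The count fell to 12 without HOAc replicate 3, to 15 without col(V) replicate 3 and to 14 without HOAc replicate 5, and rose to 58 without HOAc replicate 4. These fits and the next one had no block for the harvest, and no library was left out of the fit with the block. Deviations of the HOAc and col(V) libraries of 1 harvest correlated at r = 0.239, 0.638 and 0.883 for replicates 3, 4 and 5. In a fit of the 6 libraries alone Txnip was the 1 gene that passed, and the other named genes had adjusted p values from 0.111 (Vcam1 and Mir155hg) to 0.267 (Mmp11), with 0.123 for Nfkbid, 0.130 for Myc, 0.151 for Tgm2 and 0.201 for Axl. Without each of the 6 libraries in turn, 11 of the 36 genes passed every time, among them Txnip, Tgm2, Vcam1, Axl, Nfkbid, Myc, Idh1 and Naaa.

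Of the other named genes, Il1b did not pass without HOAc replicate 3 (adjusted p = 0.0899), col(V) replicate 3 (0.0700), col(V) replicate 4 (0.0711) or HOAc replicate 5 (0.181). Cdk5r1 did not pass without HOAc replicate 3 (0.125), col(V) replicate 4 (0.0511) or col(V) replicate 5 (0.0692). Mir155hg passed when col(V) replicate 4 was left out and had adjusted p values of 0.0597 to 0.125 without the others. Mmp11 failed without HOAc replicate 3 (0.143), col(V) replicate 3 (0.101), col(V) replicate 4 (0.0788) and HOAc replicate 5 (0.206). Without HOAc replicate 3 the values were 0.0899 for Cbx8, 0.0515 for Gimap7 and Igtp, 0.0955 for Ddah2 and Irak2, 0.160 for Nfkbiz, 0.0751 for Cd83, 0.159 for Ccr7 and 0.0515 for Dhcr7. Without col(V) replicate 3 they were 0.126 for Cbx8, 0.152 for Ddah2, 0.0607 for Gimap7, 0.0742 for Igtp, 0.0809 for Irak2 and 0.0580 for Nfkbiz. Without HOAc replicate 5 they were 0.162 for Cbx8, 0.206 for Ddah2, 0.0551 for Gimap7 and Ccr7, 0.103 for Igtp, 0.125 for Irak2 and 0.0653 for Nfkbiz. Ccr7 also failed without col(V) replicate 4 (0.0637) and 5 (0.0895), and the latter library ended the calls of Ddah2 (0.0629) and Nfkbiz (0.108).

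For col(I) the same question gave a much shorter answer (n = 3 per group). Tgm2 rose by 1.11 ± 0.20 on the log2 scale to 15.7 ± 2.67 CPM (SD), and Axl rose by 0.80 ± 0.14 to 8.80 ± 0.721 CPM. Vcam1 had a log2 change of 0.87 ± 0.18 that did not pass (adjusted p = 0.0633) and passed with the harvest as a block (0.00714), with the DESeq2 Wald test (0.00103) and without HOAc replicate 4 (0.0443). Nfkbid, Myc and Txnip, which col(V) moved, had log2 changes of 0.074 ± 0.12, -0.032 ± 0.11 and -0.029 ± 0.077, and none of the 3 passed. Myc and Txnip were chosen for this comparison after their values were seen. Of the 19 gene lists tested 0 were called, with camera adjusted p values of 0.196 for interferon-stimulated genes, 0.946 for NF-kB pathway genes and 0.901 for B cell activation genes, and 0 were called with an estimated correlation. Leaving out HOAc replicate 3 gave 2 called lists, as did leaving out HOAc replicate 5 or col(I) replicate 4.

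The 2 genes that passed for col(I) compare with 193 genes at an unadjusted p under 0.05, 9 genes with the harvest as a block, 8 higher and 1 lower, 20 with the DESeq2 Wald test and 5 with a mean of at least 5 CPM. The authors' deposited FDR passed for 30 genes, which held both of the 2 and all 9 of the block. The count was 0 in a fit of the 6 libraries alone (adjusted p = 0.371 for Tgm2 and 0.395 for Axl) or with adjustment over the 12169 genes. The adjusted p of both genes was 0.039. It was 0.329 without HOAc replicate 3, 0.0517 without col(I) replicate 3, 0.09998 without col(I) replicate 4, 0.143 without HOAc replicate 5 and 0.185 without col(I) replicate 5. In each of those 5 fits 0 genes passed, and 4 did without HOAc replicate 4. These fits and that of the 6 libraries alone had no block for the harvest. Deviations of the HOAc and col(I) libraries of 1 harvest correlated at r = 0.472, 0.861 and 0.870 for replicates 3, 4 and 5. Tgm2 and Axl were both among the 9 genes that passed with the block. In simulated data for this comparison 22.0% of genes changed 1.2-fold, 78.0% of those changed 1.5-fold and 96.0% of those changed 2-fold were found, and for col(V) the shares were 20.0%, 88.0% and 96.0%.

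The direct comparison of the 2 collagens shared no solvent control (n = 3 per group). Of the NF-kB genes 4 of 9 were higher with col(V), and the list call was lost with an estimated correlation (adjusted p = 0.146). Txnip was lower. Ccl3 was higher by 1.02 ± 0.20 and Ccl4 by 0.89 ± 0.20, both chemokines, Mir155hg by 0.74 ± 0.10 and Zc3h6, a zinc finger gene, by 0.72 ± 0.13. Nfkbid was higher by 0.70 ± 0.12, Myc by 0.70 ± 0.11, Nfkbiz by 0.41 ± 0.082, Cd83 by 0.41 ± 0.072, Ccr7 by 0.42 ± 0.080 and Vcam1 by 0.62 ± 0.17. Txnip differed by -1.16 ± 0.078, Mmp11 by -0.75 ± 0.14, Ager, a receptor of danger signals, by -0.73 ± 0.18 and Rab3a, of vesicle traffic, by -0.70 ± 0.20. Tgm2 and Axl differed by 0.45 ± 0.19 and 0.28 ± 0.13 and did not pass (adjusted p = 0.16 and 0.215), though Tgm2 passed with the harvest as a block (0.0421) and without col(V) replicate 5 (0.0445). These 2 genes were chosen for this comparison after their values were seen.

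Between the collagens, 6 gene lists were called, and these were the 6 called for col(V) against HOAc. The 2 comparisons share the 3 col(V) libraries, so their calls do not support each other. NF-kB pathway genes were higher (4 of 9 passing, 6 adjusted over the list alone, camera adjusted p = 2.0e-05, adjusted p = 0.146 with an estimated correlation), as were B cell activation genes (5 of 15 higher and 1 lower, 7 and 1 adjusted over the list alone, camera adjusted p = 2.8e-04, adjusted p = 0.106 with an estimated correlation), immediate early genes (1 of 10, 3 adjusted over the list alone, camera adjusted p = 0.00955, adjusted p = 0.63 with an estimated correlation) and ribosome biogenesis genes (2 of 26 under either adjustment, camera adjusted p = 0.00531, adjusted p = 0.781 with an estimated correlation). Resting B cell genes were lower by a median of -0.11 (1 of 11 higher and 1 lower under either adjustment, camera adjusted p = 0.0225, adjusted p = 0.477 with an estimated correlation), and interferon-stimulated genes by -0.19 (1 of 9 lower under either adjustment, camera adjusted p = 0.0411, adjusted p = 0.63 with an estimated correlation). The call for interferon-stimulated genes ended without col(V) replicate 3 (adjusted p = 0.0730), col(V) replicate 4 (0.136) or col(I) replicate 5 (0.124), and that for resting B cell genes without col(V) replicate 3 (0.108) or col(I) replicate 5 (0.0824). Immediate early genes lost it without col(I) replicate 3 (0.0692) or col(V) replicate 4 (0.0539), and ribosome biogenesis genes without col(V) replicate 4 (0.344) or col(I) replicate 5 (0.174).

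In all 273 genes passed between the collagens, 120 higher and 153 lower with col(V), and 583 with the harvest as a block, 255 higher and 328 lower. A fit of the 6 libraries alone gave 2, Txnip and Mir155hg. The other named genes that had passed with all libraries had adjusted p values from 0.0698 (Myc) to 0.230 (Birc3) there. Adjustment over the 12169 genes gave 102. The count was 105 without col(I) replicate 3, 128 without col(V) replicate 3 and 79 without col(I) replicate 5, and 67 of the 273 genes passed without each of the 6 libraries. Txnip, Mir155hg, Ccl3, Zc3h6, Mmp11, Nfkbid, Myc, Nfkbiz, Cd83 and Ccr7 were among the 67. Ager did not pass without col(V) replicate 3 (adjusted p = 0.0700), col(V) replicate 4 (0.0573) or col(I) replicate 5 (0.0732). Ccl4 did not without col(I) replicate 3 (0.0787) or 5 (0.0646). Rab3a did not without col(I) replicate 3 (0.0897), col(I) replicate 5 (0.210), col(V) replicate 3 (0.143) or col(V) replicate 4 (0.0917). For Vcam1 the values without these 4 libraries were 0.135, 0.162, 0.110 and 0.101. Tnfaip3, an NF-kB pathway gene, and Birc3 passed with all libraries and kept their call in 2 and 1 of the 6 fits without 1 library. Birc3 also failed with DESeq2 size factors (adjusted p = 0.0528) and with TMM (0.0546).

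**Figure D2:**
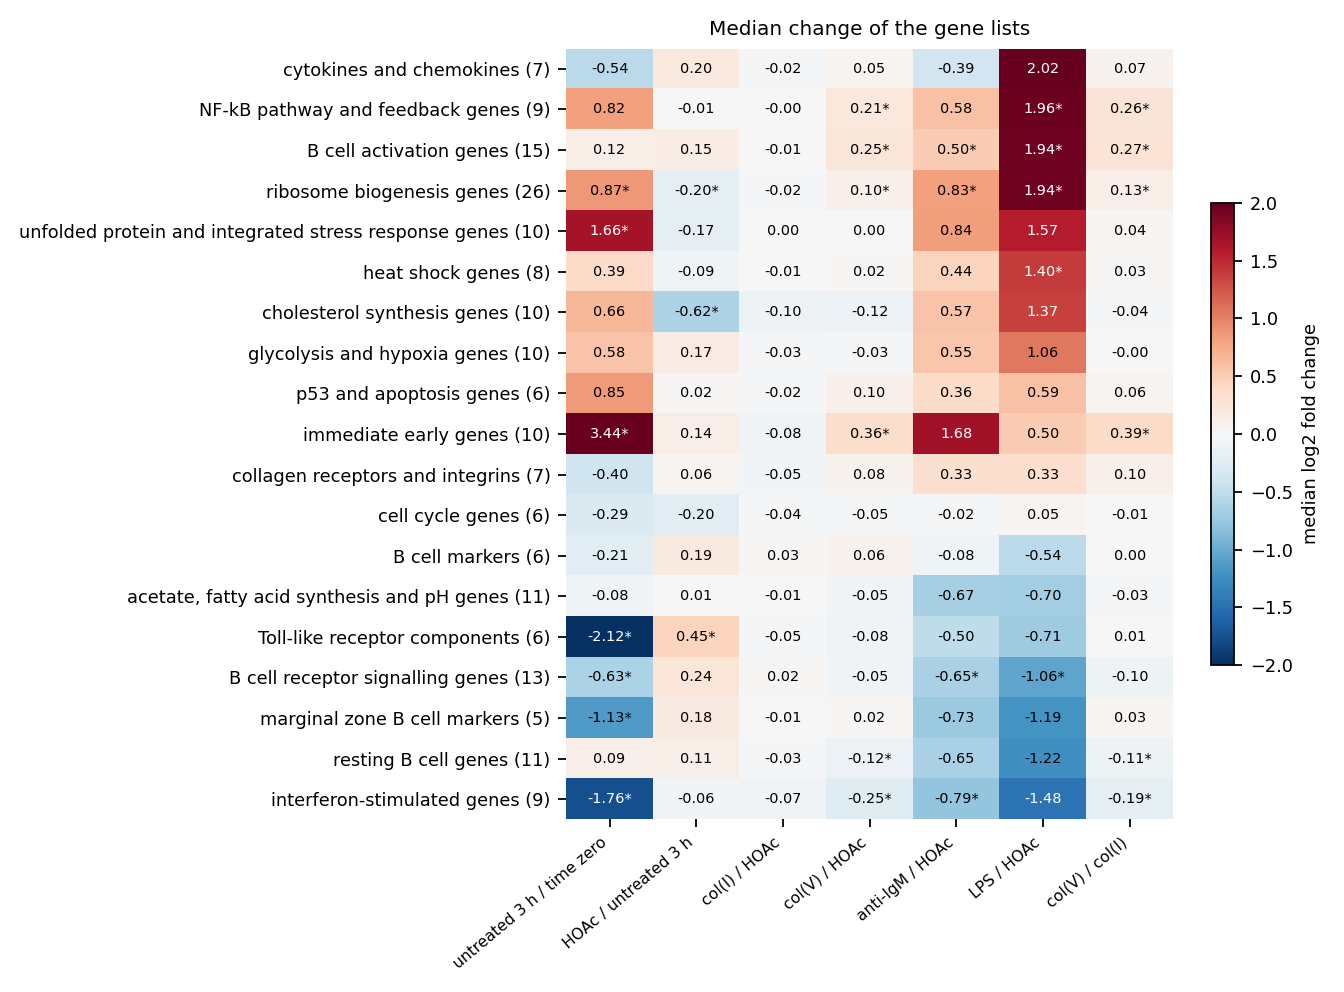
Median log2 fold change of the 19 gene lists with at least 5 measured genes (number of genes in brackets) in 7 comparisons, each named as first group / second group. Colour runs from -2 (blue) to 2 (red) and a star marks a camera adjusted p under 0.05 at the preset correlation. NF-kB pathway and feedback genes moved by 0.21 with col(V) and 1.96 with LPS.

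LPS, a ligand of Toll-like receptor 4, was 1 of the 2 reference stimuli (n = 3 per group). By list it raised NF-kB, activation, ribosome biogenesis and heat shock genes and lowered B cell receptor signalling genes at the preset correlation, while 0 lists were called with an estimated one. Among single genes, Bcl2l1, which blocks apoptosis, rose by 5.64 ± 0.20 on the log2 scale, from 11.3 ± 1.27 to 567 ± 31.0 CPM (SD), and its relative Bcl2a1d rose by 4.29 ± 0.16. Ccnd2, a cyclin of the start of division, rose by 4.27 ± 0.15 to 2634 ± 421 CPM, and Il2ra, a chain of the interleukin 2 receptor, by 4.80 ± 0.17. The secretion gene Sytl3 rose by 5.82 ± 0.30, the chemokine Ccl3 by 4.55 ± 0.19, Lrrc32, which holds latent TGF-beta, by 4.58 ± 0.35 and Cdk5r1 by 4.51 ± 0.15. Among the falls, the Polycomb gene Scml4 had a log2 change of -4.99 ± 0.16, the glycosyltransferase B3gnt8 -4.95 ± 0.25, the ubiquitin ligase March1, which removes MHC class II, -4.60 ± 0.32, Rnf144a -4.47 ± 0.20 and Ceacam1, an inhibitory receptor, -4.34 ± 0.15. Xkrx had -4.27 ± 0.25, Zfp831 -4.20 ± 0.17 and Cpt1a, which brings fatty acids into mitochondria, -4.11 ± 0.10.

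With LPS all 9 NF-kB pathway genes rose (camera adjusted p = 2.8e-04, adjusted p = 0.214 with an estimated correlation), among them Nfkbiz (4.07 ± 0.092) and Tnfaip3 (3.39 ± 0.080), and 14 of 15 B cell activation genes rose while 1 fell (camera adjusted p = 8.9e-05, adjusted p = 0.103 with an estimated correlation). The 26 ribosome biogenesis genes (camera adjusted p = 1.1e-06, adjusted p = 0.63 with an estimated correlation) and 8 heat shock genes (camera adjusted p = 0.0364, adjusted p = 0.728 with an estimated correlation) all rose. B cell receptor signalling genes fell in 12 of 13 cases (camera adjusted p = 0.0147, adjusted p = 0.459 with an estimated correlation), among them Cd22 (-2.65 ± 0.10) and Cd79a (-1.98 ± 0.072). Interferon-stimulated genes fell in 9 of 9, without a call for the list (camera adjusted p = 0.0597, adjusted p = 0.63 with an estimated correlation, 0.036 with the harvest as a block and 0.0483 without HOAc replicate 3). The unfolded protein list rose in 10 of 10 (camera adjusted p = 0.0932, adjusted p = 0.781 with an estimated correlation, 0.0388 with the harvest as a block). Counts adjusted over the list alone were equal for these 7 lists. In all 3668 of 3675 genes passed, 1832 higher and 1836 lower, and 2483 moved at least 2-fold. Since the table held only genes that the authors called for LPS, this count says nothing about the share of all genes that LPS moved. Nearly every list member in the table passed for the same reason, so these list counts show directions alone. Of 18 NF-kB pathway genes 9 were in the table, of 20 interferon-stimulated genes 9 and of 20 B cell receptor signalling genes 13. Camera set each list against this same selection.

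The other reference stimulus was anti-IgM, which cross-links the B cell receptor (n = 3 per group). By list it raised ribosome biogenesis and activation genes and lowered interferon-stimulated and B cell receptor signalling genes at the preset correlation. With an estimated correlation 0 lists were called, and the call for activation genes, of which 4 fell, hung on each HOAc library. Among single genes, Spp1, which encodes osteopontin, rose by 2.54 ± 0.39, the chemokine receptor Ccr5 by 2.34 ± 0.22, Ccl3 by 2.29 ± 0.18 and Ccl4 by 2.17 ± 0.20. Fabp5, a fatty acid carrier, rose by 2.21 ± 0.20, the calmodulin binding gene Nrgn by 2.21 ± 0.20, and the early response genes Nr4a2 and Fosl1 by 2.20 ± 0.34 and 2.18 ± 0.35. Spns2, which exports sphingosine phosphate, had a log2 change of -2.62 ± 0.28, the calcium channel Cacna1i -2.12 ± 0.21, the costimulator Icosl -1.84 ± 0.15, the homing receptor Sell -1.75 ± 0.16 and the complement regulator Cd55 -1.71 ± 0.14. Scml4, Ceacam1 and B3gnt8 had -1.79 ± 0.13, -1.78 ± 0.12 and -1.76 ± 0.18.

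Anti-IgM raised all 26 ribosome biogenesis genes (camera adjusted p = 1.1e-06, adjusted p = 0.63 with an estimated correlation) and 11 of 15 B cell activation genes, while 4 fell (camera adjusted p = 0.0477, adjusted p = 0.477 with an estimated correlation). Interferon-stimulated genes fell in 9 of 9 (camera adjusted p = 0.0108, adjusted p = 0.63 with an estimated correlation) and B cell receptor signalling genes in 10 of 13 (camera adjusted p = 0.00466, adjusted p = 0.306 with an estimated correlation). Immediate early genes rose in 9 of 10 and were not called (camera adjusted p = 0.104, adjusted p = 0.76 with an estimated correlation, 0.00759 with the harvest as a block). The unfolded protein list rose in 10 of 10 (camera adjusted p = 0.0513, adjusted p = 0.76 with an estimated correlation, 0.0181 with the harvest as a block), and resting B cell genes fell in 9 of 11 (camera adjusted p = 0.0608, adjusted p = 0.63 with an estimated correlation, 0.0336 with the harvest as a block). Counts adjusted over the list alone were equal for these lists. The call for B cell activation genes ended without HOAc replicate 3 (adjusted p = 0.0519), 4 (0.0615) or 5 (0.0523). Leaving out 1 library gave the unfolded protein list a call in 4 fits, with HOAc replicate 3 (0.0485) or 4 (0.0328) or anti-IgM replicate 3 (0.0450) or 5 (0.0499) left out, and resting B cell genes in 1, without HOAc replicate 3 (0.0483). NF-kB pathway genes, 8 of 9 higher and not called (camera adjusted p = 0.0542, adjusted p = 0.63 with an estimated correlation), were called without anti-IgM replicate 3 (0.0450) or 4 (0.0487) or HOAc replicate 5 (0.0439). In all 3668 genes passed, 1986 higher and 1682 lower, of which 418 moved at least 2-fold, and the table held only genes that the authors called for anti-IgM. Nearly every list member therefore passed by selection, and the list counts show directions alone.

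Set side by side, LPS gave higher levels than anti-IgM for activation and NF-kB genes, without a list call at an estimated correlation (n = 3 per group). Hnf1b, a homeobox gene, was higher by 5.72 ± 0.36, Bcl2l1 by 4.25 ± 0.18, Il1b by 4.04 ± 0.22 and Sytl3 by 3.87 ± 0.26. Spp1 differed by -4.59 ± 0.47, the orphan receptor Gpr137c by -4.12 ± 0.22, Txndc16, of the thioredoxin family, by -4.10 ± 0.12 and the kinase Plk2 by -3.83 ± 0.35. All 15 B cell activation genes (camera adjusted p = 7.4e-06, adjusted p = 0.078 with an estimated correlation), 9 NF-kB pathway genes (camera adjusted p = 5.9e-05, adjusted p = 0.198 with an estimated correlation) and 26 ribosome biogenesis genes (camera adjusted p = 2.0e-05, adjusted p = 0.704 with an estimated correlation) were higher with LPS, as were 8 of 8 heat shock genes (camera adjusted p = 0.0435, adjusted p = 0.743 with an estimated correlation, 0.054 with the harvest as a block). Of 10 immediate early genes 5 were lower with LPS and 0 higher, without a call (camera adjusted p = 0.337, adjusted p = 0.834 with an estimated correlation). Counts adjusted over the list alone were equal for the 5 lists. In all 3266 genes passed, 1618 higher and 1648 lower, and 1411 differed at least 2-fold.

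Against the 2 reference stimuli, col(V) left ribosome biogenesis genes lower, and against LPS also activation genes (n = 3 per group). These calls at the preset correlation were lost with an estimated one (adjusted p = 0.63 and 0.63 for ribosome biogenesis against LPS and anti-IgM, 0.106 for activation). Compared with LPS, Sytl3 differed by -5.36 ± 0.29, Bcl2l1 by -5.07 ± 0.19, Hnf1b by -4.36 ± 0.32 and Ccnd2 by -4.24 ± 0.15, while Scml4 was higher by 4.83 ± 0.16, B3gnt8 by 4.59 ± 0.25, Rnf144a by 4.40 ± 0.20 and March1 by 4.30 ± 0.32. Compared with anti-IgM, Spp1 differed by -2.33 ± 0.38, Nrgn by -2.11 ± 0.20, Fabp5 by -2.08 ± 0.20 and Nr4a2 by -1.86 ± 0.34, while Spns2 was higher by 2.36 ± 0.28, Tgm2 by 2.31 ± 0.21, Vcam1 by 2.04 ± 0.18 and Cacna1i by 2.00 ± 0.21. Counts were 3632 genes against LPS, 1824 higher and 1808 lower, and 3395 against anti-IgM, 1497 higher and 1898 lower, of which 2342 and 272 differed at least 2-fold. The excess of lower genes against anti-IgM hung on the scaling, with 1608 higher and 1672 lower under DESeq2 size factors and 1616 and 1623 under TMM.

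By list, ribosome biogenesis genes were lower with col(V) in 26 of 26 cases against LPS (camera adjusted p = 1.1e-06, adjusted p = 0.63 with an estimated correlation) and in 26 of 26 against anti-IgM (camera adjusted p = 1.7e-06, adjusted p = 0.63 with an estimated correlation). B cell receptor signalling genes were higher in 12 of 13 against LPS (camera adjusted p = 0.0135, adjusted p = 0.41 with an estimated correlation) and in 10 of 13 against anti-IgM (camera adjusted p = 0.00252, adjusted p = 0.241 with an estimated correlation). Against LPS, NF-kB pathway genes were lower in 9 of 9 (camera adjusted p = 9.1e-04, adjusted p = 0.303 with an estimated correlation), B cell activation genes in 14 of 15 (camera adjusted p = 1.8e-04, adjusted p = 0.106 with an estimated correlation) and heat shock genes in 8 of 8 (camera adjusted p = 0.0301, adjusted p = 0.718 with an estimated correlation). Against anti-IgM, glycolysis and hypoxia genes were lower in 8 of 10 (camera adjusted p = 0.0344, adjusted p = 0.63 with an estimated correlation) and unfolded protein genes in 9 of 10 (camera adjusted p = 0.0343, adjusted p = 0.76 with an estimated correlation). The call of the unfolded protein list against anti-IgM ended without col(V) replicate 3 (adjusted p = 0.0517), col(V) replicate 5 (0.0507) or anti-IgM replicate 4 (0.0507). With the harvest as a block, 3 more lists were called against anti-IgM, which were immediate early genes (adjusted p = 0.0364), interferon-stimulated genes (0.0376) and cholesterol synthesis genes (0.0277, and 0.0404 without col(V) replicate 4 and no block). Against LPS the block added cholesterol synthesis genes (0.0376) and unfolded protein genes (0.0381). Counts adjusted over the list alone were equal for the lists named here.

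The changes with col(V) ran mostly the way of both reference stimuli. Of the 36 genes 32 also passed for LPS in the same direction and 4 in the opposite direction, and for anti-IgM 33 went the same way and 3 the opposite way. Nearly all genes of the table passed for both stimuli and the HOAc libraries are shared, so independence (9.47 higher and 8.49 lower for LPS, 10.3 and 7.78 for anti-IgM) is not the value without a change. Over all genes 74.2% had the same sign as with LPS and 78.2% as with anti-IgM, where simulated unchanged groups gave 66.5% and 66.6%. Over all 3675 genes the log2 changes of col(V) correlated with those of LPS at r = 0.499 (covariance 0.149) and with those of anti-IgM at r = 0.606 (0.0783), where genes are not independent replicates. With untreated cells as control the 2 values of r were 0.060 and 0.416, where both sides share the untreated libraries and hold the response to HOAc, and no simulation was run for that control. Without col(V) replicate 4 they were 0.295 and 0.412, and without HOAc replicate 5 they were 0.333 and 0.487. In 30 simulations of unchanged groups that shared the HOAc libraries, the mean r was 0.504 and 0.498 and the mean covariance 0.00875 and 0.00857. Neither simulated group changed, so that r and the 66.5% and 66.6% came from the shared HOAc libraries alone. LPS and anti-IgM moved nearly all genes of the table here. The simulated r and share of signs are therefore no baseline for either collagen with these 2 stimuli. Shared libraries add to the covariance whatever the size of a change, so the covariances are the values to compare. For col(V) and col(I) r was 0.140 with a covariance of 0.0029 and 2 shared genes, beside a simulated 0.505 and 0.00863. Without HOAc replicate 4 they were 0.458 and 0.0145, and without col(I) replicate 4 r was -0.086. The simulation drew libraries independently, while libraries of 1 harvest varied together, so its values are no firm bound. Col(I) had 1 gene in the same direction and 1 in the opposite direction with each of LPS (r = -0.0075) and anti-IgM (r = 0.013), and the simulated mean r was 0.483 and 0.496. The sign of both turned with the library left out, to 0.292 and 0.341 without HOAc replicate 4 and to -0.308 and -0.302 without col(I) replicate 4. LPS and anti-IgM shared 3331 genes in the same direction, where independence would give 990.0 higher and 840.3 lower, and moved 331 in opposite directions (r = 0.766), a share raised by the way the table was selected.

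These overlaps moved with the count for the collagens. With the harvest as a block col(V) shared 185 genes with LPS and 196 with anti-IgM. The 2 overlaps were 9 and 10 without HOAc replicate 3, 12 and 13 without col(V) replicate 3, 11 and 12 without HOAc replicate 5, and 53 and 55 without HOAc replicate 4. Those of col(I) with col(V), LPS and anti-IgM were 0 without HOAc replicate 3 or 5 or any col(I) library. The overlap with col(V) was also 0 without col(V) replicate 3, that with LPS without LPS replicate 3 or 5, and that with anti-IgM without any anti-IgM library, while it was 2 without HOAc replicate 4 and with the harvest as a block. With untreated cells in place of HOAc as control the overlaps of col(V) were 523 with LPS, 645 with anti-IgM and 1157 with col(I), and those of col(I) were 398 and 492.

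Col(V) against col(I), which shares no library with the reference comparisons against HOAc, correlated with anti-IgM against HOAc at r = 0.541 and with LPS against HOAc at r = 0.456 across genes. Among the 331 genes that LPS and anti-IgM moved in opposite directions, 52 had an unadjusted p under 0.05 for col(V) against HOAc, of which 45 went the way of anti-IgM and 7 the way of LPS.

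**Figure D3:**
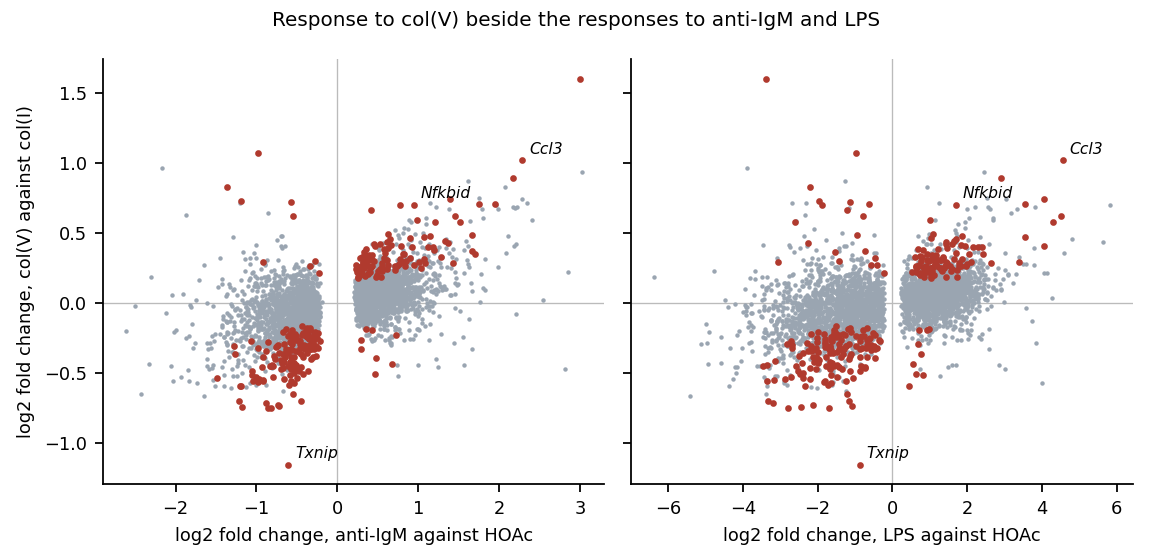
Log2 fold change of col(V) against col(I) (vertical axes) beside that of anti-IgM against HOAc (left, horizontal axis) and of LPS against HOAc (right, horizontal axis) for 3675 genes. Red points are the 273 genes that passed for col(V) against col(I) and grey points are the others. The correlation across genes is 0.541 on the left and 0.456 on the right, and the gap around 0 on the horizontal axes comes from the selection of the table.

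Markers of other cell types were few in the table. Of the monocyte and macrophage markers 3 of 16 were measured, which were Vcam1, Adgre1 and Cd68. With col(V) against HOAc, Adgre1 had a log2 change of 0.25 ± 0.24 and Cd68 of 0.18 ± 0.088, at 7.32 ± 2.27 and 13.1 ± 0.871 CPM (SD), and neither passed, while Vcam1 rose. In culture all 3 fell, where Adgre1 fell by 1.496 and Cd68 fell by 0.46 on the log2 scale. The 1 measured T cell marker of 18, Il7r, had a log2 change of 0.68 ± 0.27 with col(V), which did not pass over all genes (adjusted p = 0.226) and passed with the harvest as a block (0.0337). Of 2 of 9 dendritic cell markers, Zbtb46 had 0.33 ± 0.14 and Flt3 0.26 ± 0.13. Of 3 of 8 plasma cell markers Prdm1 had 0.13 ± 0.13, Xbp1 0.10 ± 0.12 and Sdc1 -0.16 ± 0.21. The 1 stromal and endothelial marker of 14, Pecam1, had -0.17 ± 0.12. None of these 6 genes passed.

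Of the remaining lists, 0 of 6 B cell markers, 5 marginal zone B cell markers, 13 B cell receptor signalling genes, 10 unfolded protein genes, 8 heat shock genes, 10 glycolysis and hypoxia genes, 11 acetate, fatty acid synthesis and pH genes and 6 cell cycle genes passed with col(V), and 0 when adjusted over the list alone. With the harvest as a block 1 B cell marker and 2 genes of the acetate list fell and 1 unfolded protein gene rose. Of 6 p53 and apoptosis genes 0 passed and 1 fell adjusted over the list alone. Of 4 inflammasome and danger signalling genes 0 passed and 1 rose and 1 fell adjusted over the list alone. Of 2 antioxidant and metallothionein genes 0 passed under either adjustment. The lists of mitochondrially encoded genes, ribosomal protein genes, NK cell markers, neutrophil markers, erythroid markers and platelet markers had 0 genes in the deposited table and were not analysed here.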

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

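The tests on the direction of genes that LPS and anti-IgM moved apart, on the HOAc libraries and on macrophage markers were chosen after the result was seen, while the correlation without shared libraries, the test on acid and the splits of the libraries were written before. The gene Pdcd1lg2, a ligand of PD-1, stood first among the names, with no line of counts above it. It therefore had no counts and took part in no comparison. The deposited statistics alone showed a signal there. The authors' log2 fold change of Pdcd1lg2 was 0.41 for col(V) against HOAc (FDR 2.7e-07), 1.57 for anti-IgM (FDR 4.8e-127), 1.65 for LPS (FDR 4.1e-142) and 0.043 for col(I) (FDR 0.992). No biological explanation was tested for it, and libraries could not be compared.

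The first pattern weighed was that the changes with col(V) mostly ran with those of anti-IgM and LPS, though Tgm2 and Vcam1 went against both. Shared HOAc libraries alone would leave no correlation where no library is shared, and col(V) against col(I) correlated with anti-IgM against HOAc at r = 0.5412 and with LPS against HOAc at 0.4558. A weak LPS response to endotoxin in the col(V) preparation would move genes the way of LPS where LPS and anti-IgM part. Of 52 such genes with an unadjusted p under 0.05 for col(V) against HOAc, 13.46% went the way of LPS, and of 85 such genes for col(V) against col(I) 24.71% did. The tables thus argue against both explanations as the whole cause. Only 1 dose and 1 time of LPS were measured, so the course of a lower dose stays open. A candidate explanation is that col(V) may act on B cells in part as cross-linking of the B cell receptor does. This hypothesis was found on these same data and was not tested. Less acid in the col(V) wells, weighed below, is not told apart from it. Of the 96 genes that HOAc changed at least 2-fold, 81 passed the opposite way with anti-IgM against HOAc and 14 the same way. Col(V) given to B cells in which signals of that receptor are blocked would test the hypothesis.

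The second pattern was that Tgm2 and Axl were higher with both collagens, and Vcam1 with col(V) and, with the harvest as a block, with col(I). More macrophage RNA in the collagen wells could raise Vcam1, a member of the macrophage list. It was predicted to raise the other measured members of the list by about as much as the smallest of the 3 rises. The larger log2 change of Adgre1 and Cd68 with col(V) was 0.2519, and the smallest of the 3 genes, Axl, lay above Adgre1 by 0.8255 ± 0.2781 (SE) and above Cd68 by 0.8999 ± 0.1645. For col(V) these values argue against a rise shared equally by the measured macrophage markers. In culture, however, Vcam1, Adgre1 and Cd68 fell by unlike amounts, so an equal rise was not assured and more macrophage RNA is not excluded. For col(I) the markers were not set against the rises. For col(V) the tables argue against a single low HOAc library as the cause. Without each HOAc library in turn 3 of the 3 genes passed, and the smallest log2 change was 0.9551, for Axl. For col(I) 0 of the 3 genes passed in all of these fits, which had no block for the harvest. The fold held, so no single HOAc library carried it. Without HOAc replicate 3 the log2 change of Tgm2 went from 1.11 ± 0.20 to 1.02 ± 0.23, that of Vcam1 from 0.87 ± 0.18 to 0.78 ± 0.20 and that of Axl from 0.80 ± 0.14 to 0.6774 ± 0.1451. In that fit the adjusted p in edgeR's quasi-likelihood test, over the 3675 genes from which these 3 were picked, was 0.329, 0.563 and 0.329. Without HOAc replicate 5 it was 0.143, 0.331 and 0.143. All 3 genes passed without HOAc replicate 4 (0.0443, 0.0443 and 0.0364), while Vcam1 had not passed with all libraries. A low shared by the HOAc libraries cannot be tested by leaving 1 out, and was not told apart from an effect of either collagen. In each harvest all 3 genes were higher with HOAc than in untreated cells, and higher with each collagen than with HOAc. The HOAc libraries were thus not low beside untreated cells. HOAc itself moved 1587 genes, however, so untreated cells cannot decide the question. Adgre1 was measured at 6.17 CPM with HOAc, the sort for CD19 would remove most macrophages, and a change of state within a few remaining macrophages stays open, as does a response of the B cells. Other abundant macrophage genes were not in the table.

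The last pattern was that col(V) moved genes back that HOAc had moved. Of the 96 genes that HOAc changed at least 2-fold, 83.33% (80 genes) went the other way in col(V) against col(I), with a slope of -0.1472, and 13 of the 14 that passed did so. Txnip lay just under the 2-fold limit and was not among these genes. In col(V) against HOAc 2 of the 96 genes passed the other way and 0 the same way. Such moves were not seen with col(V) alone. Against HOAc 84.4% of these genes went the other way with col(V), 53.1% with col(I), 80.2% with LPS and 85.4% with anti-IgM, but those comparisons subtract the same HOAc libraries, which favours opposite signs, and over all genes the shares were 63.4%, 47.8%, 69.7% and 69.5%. Less acid in the col(V) wells was predicted to give such a share and also a steeper slope, which was not reached, so it cannot be told apart from an effect of col(V) with these data. The pH of the wells was not given.

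Each count of genes that passed was set against the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real counts were 2994, 1587, 36, 2, 3668, 3668, 273, 3632, 3395 and 3266 in the order of the comparisons above (culture, HOAc, col(V), col(I), LPS and anti-IgM, then col(V) against col(I), LPS and anti-IgM, and LPS against anti-IgM), and the highest count of the other splits was 0 in each, also among those that part all 3 harvests. Splits that mix the groups carry the group difference in their spread, which lowers their counts.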

How the results depend on the processing

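TMM over the deposited genes was the scaling planned before the data were examined. The library sizes of the authors replaced it afterwards, when the table proved to be a selection, and TMM was kept as an alternative. Adjustment over all genes that the authors tested and leaving out libraries for gene lists and overlaps were chosen after the results were seen, and the other alternatives were fixed before. Counts of genes for culture (2883 to 2988 without each library), HOAc (1205 to 1722), LPS (3656 to 3661), anti-IgM (3592 to 3657), col(V) against LPS (3599 to 3625), col(V) against anti-IgM (3082 to 3388) and LPS against anti-IgM (3190 to 3232) stayed within 1.5 times under every alternative run. No result on a named gene that passed turned in direction under any alternative that was run. The larger side of the HOAc count turned, from 868 higher and 719 lower to 764 and 850 with DESeq2 size factors. That of LPS against anti-IgM turned from 1618 and 1648 to 1659 and 1584 with the same factors, that of col(V) against LPS from 1824 and 1808 to 1587 and 1711 at 5 CPM, and that of col(V) against col(I) from 120 and 153 to 146 and 132 without col(V) replicate 4. Others among the comparisons with nearly even sides turned too. At 5 CPM the median log2 change over all genes turned from -0.23 to 0.38 for LPS and from 0.072 to -0.32 for col(V) against LPS.

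The counts for the collagens moved. With the harvest as a block 205 genes passed for col(V) against HOAc, 9 for col(I) against HOAc and 583 for col(V) against col(I), as the block takes differences between harvests out of the spread. In fits of the 2 groups alone 1, 0 and 2 passed, with fewer libraries to estimate the spread. The Wald test of DESeq2 gave 155 for col(V) and 20 for col(I), and the cause was not tested. Adjustment over the 12169 genes gave 17, 0 and 102. It adjusted the p-values of the genes in the table for 12169 tests, as if all other p-values were larger, so these counts are lower bounds. A mean of at least 5 CPM gave 5 for col(I), with fewer genes tested. Without 1 library the counts ran from 12 to 58, from 0 to 4 and from 79 to 318, in fits that had no block for the harvest.

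With an estimated correlation 0 lists were called in culture, HOAc, col(V), LPS, anti-IgM, col(V) against col(I), col(V) against LPS, col(V) against anti-IgM and LPS against anti-IgM. That setting widens the spread expected of a list by the correlation left among its genes after the fit. The fit had no block for the harvest, so differences between harvests can enter that correlation. An estimated correlation was not run with the block. With the harvest as a block 7 lists were called for anti-IgM and 7 for col(V) against anti-IgM. Without 1 library 0 to 2 lists were called for col(I) and 3 to 6 for col(V) against col(I).

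Overlaps followed the counts. The block gave 185 genes for col(V) and LPS, 196 for col(V) and anti-IgM and 2 for col(I) and anti-IgM. With untreated cells as control they were 523, 645, 1157 for the 2 collagens, 398 for col(I) and LPS and 492 for col(I) and anti-IgM, and the cause was not tested. At the same time r fell from 0.499 to 0.060 for col(V) and LPS and from 0.606 to 0.416 for col(V) and anti-IgM, while it rose from 0.140 to 0.873 for the 2 collagens. Without 1 library the overlaps ran from 9 to 53, 10 to 55, 0 to 3, 0 to 1 and 0 to 2 in that order, and r for the 2 collagens ran from -0.086 to 0.458.

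For the 1001 results on single named genes, 12659 of 12999 values under an alternative stayed on their side of the threshold, 205 no longer passed and 135 came to pass. Of these changes 184 came from leaving out 1 library (139 lost, 45 gained), 56 from fits of the 2 groups alone, 55 from the block (all gained), 22 from the Wald test of DESeq2, 13 from DESeq2 size factors, 9 from TMM and 1 from the filter at 5 CPM. Removing the filter changed nothing, since it removed no gene. The pseudocount named among the alternatives was not run, as the values were counts. At the depth, spread and group size of these libraries 20.0% of simulated 1.2-fold changes were found for col(V). Depth was not varied on its own, so its share in this limit was not tested.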

Other observations

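All lists in this part were formed from gene symbols after the results were seen, and so were their tests. The authors had called every gene of the table for both LPS and anti-IgM, so for these stimuli the counts show directions alone. Set directly against anti-IgM, LPS gave lower levels in 17 of 18 lysosomal genes and higher levels in 0 (camera adjusted p = 2.4e-04, and 0.416 with an estimated correlation). All 11 measured subunits of the proton pump rose with anti-IgM, by a median of 0.67 (adjusted p = 6.1e-04 over 80 tests, and 0.416), while 5 rose and 6 fell with LPS (adjusted p = 0.686, and 0.888). Of 7 cathepsins 7 fell with LPS, by a median of -1.30 (adjusted p = 0.0350, and 0.515), and 4 rose and 3 fell with anti-IgM (0.775, and 0.892). Over the 18 genes together 15 rose with anti-IgM (0.00521, and 0.416) and 13 fell with LPS (0.112, and 0.561). With col(V) 0 of the 18 passed in edgeR's quasi-likelihood test or with the harvest as a block, 15 had a positive change, and the median was 0.091 (adjusted p = 0.0072, and 0.416).

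Genes that charge tRNAs with amino acids rose in culture in 15 of 16 cases, by a median of 1.83 (adjusted p = 1.7e-09, and 0.416 with an estimated correlation), and all 16 rose with LPS and with anti-IgM. All 23 measured mitochondrial ribosomal protein genes rose with LPS (median 1.28, adjusted p = 3.7e-04, and 0.561) and with anti-IgM (0.42, 0.0160, and 0.715), and 12 fell with HOAc (-0.24, 3.7e-04, and 0.561). Of 20 proteasome subunits 16 rose and 4 fell with LPS (0.0160, and 0.621) and with anti-IgM (0.369, and 0.881). GTPases of the GIMAP family fell in 7 of 7 cases in culture (-0.95, 1.7e-04, and 0.416) and in 7 of 7 with anti-IgM (-0.66, 3.7e-04, and 0.416), while 6 rose with HOAc (0.46, 2.4e-04, and 0.416). With LPS 5 of them rose and 2 fell (0.928, and 0.963). Histone genes fell in 7 of 7 cases with LPS (-2.77, 0.0229, and 0.515) and with anti-IgM (-1.14, 0.0153, and 0.497), and 5 of 7 rose with HOAc (0.83, 0.0196, and 0.497). With col(V) against HOAc 0 of the 23 mitochondrial ribosomal protein genes passed and 18 had a positive change (0.12, 7.4e-04, and 0.561). Of the 7 GIMAP genes 1 fell with col(V) and 0 had a positive change (-0.11, 0.00284, and 0.416). The tRNA, proteasome and histone lists were not called with col(V) (camera adjusted p = 0.336, 0.775 and 0.669).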
